A study of Drosophila melanogaster with 46 samples.

How the data were processed

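RNA from whole female wandering third-instar larvae of Drosophila melanogaster was depleted of ribosomal RNA and sequenced by the submitters, with 8 larvae pooled per replicate. The labels place 46 libraries in 13 groups, listed with their sizes in the results. Salmon and DESeq2 are named, without versions, in the submitters' processing notes, which also name the dm6 genome build. Quantification settings and the use of strand are not given in the sources used here.

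The data analysed were 10 tables of comparisons made by the authors, each with a gene symbol and 5 columns of values. The mean signal per gene, a normalised count averaged over libraries per the file headers, was the same for a gene in every table and so covers all libraries together. Fold changes and their standard errors were deposited on the log2 scale by the authors. The p-value and adjusted p-value of each gene were those deposited by the authors. Every listed gene had an adjusted p under 0.01 and an absolute log2 fold change above 1, so each table holds only the genes past both limits and a gene that is not listed has no value here. Dividing the log2 fold changes by their standard errors did not give the p-values of the same genes, and some fold changes exceeded 10. Such values are fitted ones, whose cause was not tested here, and they are not read as the size of a change. The shrinkage or prior behind these fits is not given in the sources used here. No values per library were analysed here, so sequencing depth is unknown, no library could be left out, and no spread between replicates was computed. The libraries are separate pools of larvae per the labels, and the authors' p-values measure the spread between those pools.

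The number of genes tested was recovered from each table as the ratio of adjusted to raw p for the gene with the smallest p. This gave a whole number in 9 tables. For the comparison of temperatures in PBac/Df it did not, and the 13986 protein-coding genes of the annotation stood in for it. The rank implied by the last listed gene gave a lower bound on the number of genes passing the adjusted p limit at any fold. Of the 4620 genes listed in at least 1 table, 4609 matched a symbol in the Ensembl annotation of the same assembly as dm6. All 4609 were annotated as protein-coding, so non-coding list members such as roX1 and roX2 may not have been testable. Coordinates are from that annotation and count from 1.

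Genes were called at an adjusted p threshold of 0.05, which the limits of the tables already exceed. Overlaps between the 7 comparisons at 25 °C were tested with one-sided Fisher's exact tests per direction, with the smaller number of genes tested as background and Benjamini-Hochberg adjustment over 42 tests. Gene lists were tested in the same way, over 350 tests of 25 lists. Members that a table did not list counted as not called, and 716 of the 734 list entries matched the annotation. Adjusted over the list alone, with members not listed taken at a p of 1, the counts of called members differed in 0 of the 350 tests. Odds ratios had 0.5 added to each cell. Differences between comparisons were tested as z, the difference of the authors' log2 fold changes over the root of the summed squared standard errors, two-sided, with Benjamini-Hochberg adjustment over the genes in both tables. The test therefore leaves out any gene listed in one table and not in the other. Because the fold changes and standard errors do not give the authors' p-values and may be shrunken, the z p-values and the counts of differing genes are approximate. Direction near l(3)mbt, Set8 and the histone cluster was tested within 500 kb with two-sided Fisher's exact tests. List members called in only 1 of 2 comparisons were compared with all other genes called in only 1 of them by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 24 tests, since an exact McNemar test, tried first, takes no account of the longer of 2 tables.

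For pairs that share control libraries, unchanged groups were simulated 200 times at the correlation set by the numbers of libraries, and called at the largest p listed in each table. The fold limit was not part of the simulation. The controls were not split, because no values per library were analysed.

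The gene lists, the tests of lists, overlaps and loci, the z tests of the alleles and of 29 °C, and the rule for named genes were fixed before the data were examined. The McNemar tests and the Fisher's tests beside them, the simulation, the z tests between histone substitutions and between Set8 contrasts, and the tests of lists and of opposite directions at 29 °C were added afterwards. The rule took Set8, l(3)mbt, Hmt4-20 and histone genes wherever listed. It then took the 6 higher and 6 lower genes with the largest absolute log2 fold change among those with a mean signal of at least 50. From each list with at least 3 called members it took those with the smallest adjusted p, up to 4. It also took 10 genes shared by Set8null, GM76/Df and PBac/Df but not listed in WT/Df, and the 6 genes with the smallest adjusted p of each z test. A gene named for 1 comparison was also given for others where useful. Genes named outside the rule are marked as chosen after their values were seen. The lists covered H4K20 methylation, LINT and dREAM complexes, the piRNA pathway, germline and oogenesis, meiosis, testis, male-specific genes, yolk and chorion, Hippo signalling, cell cycle, DNA damage and apoptosis, immunity, and stress. They also covered detoxification, larval serum and fat body, ecdysone response, glue, cuticle, digestion, neurons, neuroblast and imaginal patterning, muscle, hemocytes, histones, and background and pigment genes.

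Alternatives were a mean signal of at least 50, Bonferroni adjustment, another background, other windows, and subtraction of the covariance from shared controls. Stricter limits of 0.001 on the adjusted p and 2 on the log2 fold change, and removal of genes listed in WT/Df, were added after seeing the data. The 150 tests of lists at 29 °C were adjusted together. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on 20 simulated pairs of tables modelled on Set8null against Oregon-R, with 12928 genes of which 200 changed. The number of genes tested was recovered in 20 of 20 tables, and z found 68% of the true differences of 3 log2 units with 0.25 false ones per pair. Those z figures came from whole simulated tables, where the differences were genes changed in a single table and p followed fold over error. The z tests reported here used only genes listed in both tables, so the figures do not apply to them. Random lists gave a Fisher p under 0.05 in 2.5% of 1000 draws. Genes with near-identical copies, such as LysB, LysD and LysE, ng1 and ng2, the Hsp70 genes, the Mst84D genes and the trypsins, are uncertain, since reads may be split between copies.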

Results

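The series measured RNA from whole female wandering larvae to ask how the histone methyltransferase Set8, its catalytic activity, the chromatin protein L(3)mbt and histone H4 lysine 20 itself act on gene expression. Wild-type Oregon-R (4 libraries) served as control for the Set8null mutant (4) and for 3 genotypes over the deficiency Df(ED10966). Those carried a wild-type l(3)mbt copy (WT/Df, 3), the GM76 allele (GM76/Df, 4) or a PBac insertion allele (PBac/Df, 3). Larvae with a Set8rg transgene in the Set8 mutant background (3) were compared with a Set8wt transgene (4), a contrast called Set8RG here. Larvae lacking the histone gene cluster and carrying 12 copies of a histone transgene had either wild-type H4 (HWT, 4) or the substitutions H4K20A (3) or H4K20R (4). The 3 deficiency genotypes were also raised at 29 °C (3, 4 and 3 libraries). Values are the authors' log2 fold changes ± standard error, and adjusted p-values of lists and overlaps are from one-sided Fisher's exact tests with Benjamini-Hochberg adjustment, unless stated. The depth of the libraries is unknown, and only genes past the limits of the tables carry values. A gene that is not listed is not shown to be unchanged, and values above 10 in size are fitted ones that are not read as a size. Because the RNA came from whole larvae, a list that moved may reflect a changed share of a tissue as well as a change within its cells.

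**Figure D1:**
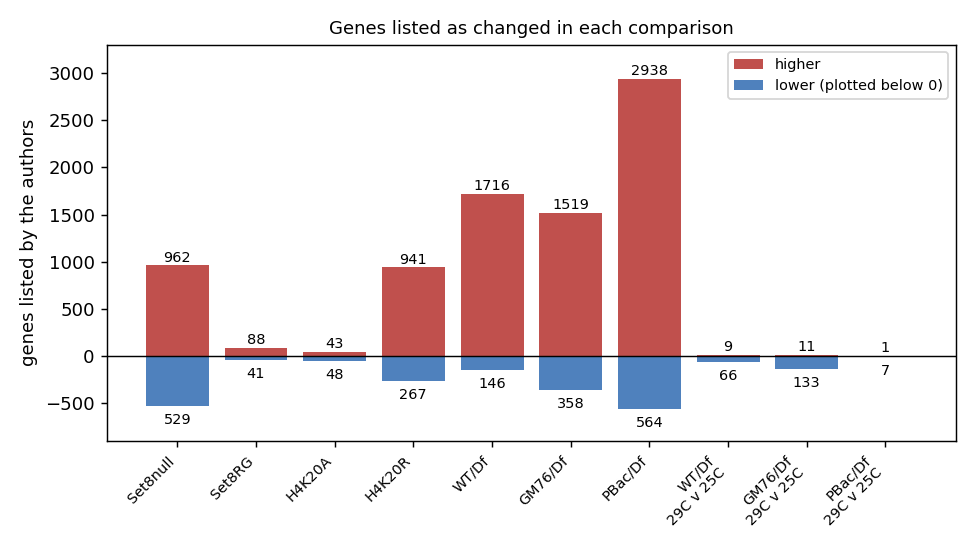
Number of genes that the authors listed as higher (bars above 0) and lower (bars below 0, with their numbers) in each of 10 comparisons. PBac/Df had the most, 2938 higher and 564 lower, and the comparisons of 29 °C with 25 °C, Set8RG and H4K20A had fewer than 150 each.

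In larvae without Set8, cell division and imaginal patterning genes were lower, and stress, digestive, detoxification and cuticle genes were higher. Set8 itself, at 3R 14316038 to 14320494, was 17.1-fold lower in Set8null in the authors' deposited table (log2 -4.10 ± 0.12). Of the 40 cell cycle genes, 12 fell and none rose (one-sided Fisher's exact test, adjusted p = 7.0e-07). They included the mitotic cyclins CycA (-1.48 ± 0.10) and CycB (-1.35 ± 0.09), the mitotic kinase polo (-1.38 ± 0.09) and the spindle gene asp (-1.44 ± 0.10) in the authors' deposited table. Of 32 neuroblast and imaginal patterning genes, 16 fell and 1 rose (adjusted p = 1.4e-12). In the authors' deposited table, the eye and leg patterning genes eya (-1.81 ± 0.16) and dac (-2.48 ± 0.22), the Notch target E(spl)mgamma-HLH (-2.57 ± 0.22) and klu (-1.30 ± 0.13) were among them. The wing selector vg (-2.57 ± 0.24) and ds (-1.25 ± 0.20) also fell, while Ilp8, a relaxin-like peptide released by growth-disturbed discs, rose by 8.75 ± 0.81 in the authors' deposited table. These 3 were the called members of the 21 Hippo list genes. Meiosis genes fell (5 of 23, adjusted p = 0.016), as did 5 of 27 piRNA genes (adjusted p = 0.031), while 1 piRNA gene rose. The authors' deposited table had krimp at -2.39 ± 0.30, del at -1.79 ± 0.26, piwi at -1.18 ± 0.25 and AGO3 at 1.49 ± 0.25.

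Stress genes rose in Set8null (10 of 30, adjusted p = 0.00043), led in the authors' deposited table by the humoral stress genes TotB (5.85 ± 0.84) and TotC (4.18 ± 0.61). Immune genes went both ways, with 10 of 49 higher (adjusted p = 0.021) and 8 lower (adjusted p = 0.0069). The Bomanin genes BomBc3 (9.68 ± 1.32) and BomS3 (6.27 ± 0.83) rose and the amidases PGRP-SC2 (-3.70 ± 0.30) and PGRP-SC1a (-6.68 ± 0.88) fell in the authors' deposited table. The DNA damage and apoptosis list had 3 of 20 genes higher (adjusted p = 0.72), egr (1.20 ± 0.11), Xrp1 (1.51 ± 0.17) and Corp (1.31 ± 0.23) in the authors' deposited table. Digestive enzymes (20 of 53 higher, adjusted p = 1.2e-08), cuticle genes (20 of 67, adjusted p = 7.8e-07) and detoxification genes (20 of 73, adjusted p = 3.4e-06) rose, while 3, 2 and 4 of them were lower. Examples from the authors' deposited table were betaTry (5.07 ± 0.31), Jon25Biii (4.70 ± 0.26), Cpr65Au (5.67 ± 0.81) and the cytochrome P450 genes Cyp4p2 (5.76 ± 0.23) and Cyp6w1 (5.84 ± 0.47). The hemocyte list had 5 of 21 genes lower (adjusted p = 0.011), with LanA (-1.12 ± 0.12), eater (-2.12 ± 0.24) and NimC1 (-1.55 ± 0.18) lower and the prophenoloxidase PPO3 (2.76 ± 0.30) higher in the authors' deposited table. Of 13 background and pigment genes, 3 were higher and 1 lower (adjusted p = 0.34 and 1), the lower one being the eye colour gene w, and the labels give a yw background for the mutant and not for Oregon-R. The largest changes with a standard error under 0.5 in the authors' deposited table were losses of CG3588 (-9.36 ± 0.49) and CG3397 (-8.33 ± 0.40). In all, the authors' DESeq2 table listed 1491 of 12928 genes tested, 962 higher and 529 lower, and at least 4005 genes passed its adjusted p limit at any fold. At an absolute log2 fold change of at least 2 the count was 591, no cell cycle gene was called, and the calls of the cell cycle, meiosis, piRNA and hemocyte lists ended. With listed genes as background, the calls of the immune list in both directions and of the meiosis, piRNA and hemocyte lists ended. The calls of piRNA and of higher immune genes also ended at a mean signal of at least 50, and those of meiosis and of lower immune genes at an adjusted p limit of 0.001.

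The Set8RG contrast, which asks about catalytic activity, gave a smaller set that included stress genes and Ilp8. In the authors' deposited table Ilp8 rose by 6.40 ± 0.89, TotB by 4.71 ± 0.90, TotC by 2.99 ± 0.72 and TotA by 1.85 ± 0.32. Stress genes were 3 of 30 higher (one-sided Fisher's exact test, adjusted p = 0.013). The integrin gene ItgaPS4 (4.48 ± 0.53), the sugar transporter family gene CG1208 (4.37 ± 0.55), CG43133 (4.65 ± 0.94) and Cyp4e3 (4.10 ± 0.85) were also among the largest rises in the authors' deposited table. Lower genes in the authors' deposited table included CG3397 (-8.06 ± 0.46), Cyp9f3 (-2.50 ± 0.22) and the larval storage protein Lsp1alpha (-2.43 ± 0.60). Cuticle genes were 3 of 67 lower (adjusted p = 0.015), Lcp3 (-2.36 ± 1.14), Lcp4 (-1.05 ± 0.64) and Lcp9 (-2.15 ± 1.41) in the authors' deposited table. Detoxification genes were 3 of 73 lower (adjusted p = 0.018) and 3 higher, with Cyp4d1 (-1.31 ± 0.24) and Cyp6d5 (-1.44 ± 0.27) lower and GstE6 (2.84 ± 0.48) higher in the authors' deposited table. The fat body list had 2 of 20 genes lower (adjusted p = 0.018). The hemocyte list had 2 of 21 genes higher (adjusted p = 0.075), and the cell cycle and patterning lists had no called member. CG31988 (-21.76 ± 2.36) and CG10252 (-20.69 ± 2.55) had fitted values above 10 in size in the authors' deposited table. The authors' DESeq2 table listed 129 of 11332 genes tested, 88 higher and 41 lower, and Bonferroni adjustment left 83. The list calls of lower genes each ended under at least 1 alternative: fat body at a log2 fold change of at least 2, cuticle at 0.001 and with listed genes as background, and detoxification under all 3.

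With the H4K20A substitution few genes were listed, with lysozymes lower and new glue genes higher. The authors' deposited table had LysD 32.0-fold lower, LysB at -4.55 ± 0.62 and LysE at -4.01 ± 0.54, neighbours on 3L whose reads may be shared. The immune list had 3 of 49 genes lower (one-sided Fisher's exact test, adjusted p = 0.0094) and 1 higher, PGRP-SB1 (1.75 ± 1.12) in the authors' deposited table. The 3 lower genes were these lysozymes, so the test counted neighbours with possibly shared reads as separate genes. Glue genes were 3 of 12 higher (adjusted p = 0.00013), ng1 (4.33 ± 0.91), ng2 (2.94 ± 1.38) and ng3 (1.42 ± 0.88) in the authors' deposited table. The testis list had 4 of 39 genes lower (adjusted p = 0.00024). These were ProtB (-20.90 ± 2.43), Mst84Da (-20.09 ± 2.69), S-Lap2 (-3.90 ± 2.99) and loopin-1 (-2.63 ± 2.36) in the authors' deposited table. At a mean signal of at least 50, the receptor family gene mthl8 (10.59 ± 1.06), CG33267 (5.59 ± 1.53), CG4757 (3.45 ± 0.88), CG30026 (3.22 ± 0.41) and CG44624 (3.15 ± 1.78) were the other largest rises in the authors' deposited table. Large falls in the authors' deposited table were CG10252 (-21.15 ± 2.51), CG46463 (-15.76 ± 9.30), CG32640 (-10.80 ± 1.34), CG42717 (-8.67 ± 2.15) and Jig (-4.98 ± 1.30). The authors' DESeq2 table listed 91 of 11598 genes tested, 43 higher and 48 lower. Bonferroni adjustment left 55, the testis and glue calls ended at an adjusted p limit of 0.001, and the immune call ended with listed genes as background.

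The H4K20R substitution was accompanied by higher detoxification, digestive, cuticle, muscle and immune genes and lower glue and ecdysone-response genes. Of 73 detoxification genes, 33 rose and none fell (one-sided Fisher's exact test, adjusted p = 1.5e-15), among them Cyp4e3 (5.87 ± 0.77), Cyp6a8 (3.47 ± 0.46), Cyp6a17 (3.00 ± 0.44) and GstD3 (1.23 ± 0.20) in the authors' deposited table. Digestive enzymes were 23 of 53 higher (adjusted p = 7.3e-11) and 2 lower, with the maltases Mal-A3 (4.39 ± 0.63) and Mal-A4 (3.47 ± 0.52) and the proteases Ser6 (3.34 ± 0.49) and kappaTry (4.19 ± 0.61) higher in the authors' deposited table. Cuticle genes were 23 of 67 higher (adjusted p = 1.2e-08) and 3 lower, with Lcp65Ag3 at 6.85 ± 1.24 and Cpr78Cc at 5.64 ± 0.96 in the authors' deposited table. Muscle genes were 8 of 26 higher (adjusted p = 0.0052), including myosin heavy chain Mhc (1.92 ± 0.63), Act87E (1.74 ± 0.33) and TpnC47D (2.97 ± 0.65) in the authors' deposited table. Immune genes were 13 of 49 higher (adjusted p = 0.00068) and none lower, led by AttD (4.34 ± 0.54), PGRP-LF (1.28 ± 0.27), BomT2 (3.54 ± 0.79) and the defensin Def (3.42 ± 0.90) in the authors' deposited table. Of 46 ecdysone-response genes, 9 fell and 1 rose (adjusted p = 8.7e-06). The authors' deposited table had the early genes br at -1.28 ± 0.34 and Eip75B at -1.21 ± 0.34, Eig71Eg at -4.27 ± 1.60 and the mid-prepupal factor ftz-f1 at 1.62 ± 0.28. Of 12 glue genes, 6 fell (adjusted p = 1.5e-06) and 3 rose. The glue protein gene Sgs5 (-1.76 ± 0.37) fell and ng1 (6.05 ± 0.82), ng2 (5.50 ± 0.85) and ng3 (3.43 ± 0.52) rose in the authors' deposited table. At a mean signal of at least 50, Jig (-6.46 ± 1.35), nol (-6.13 ± 0.95) and CG32640 (-5.27 ± 0.54) were the largest falls, and CG13230 (7.65 ± 1.41), CG14205 (7.61 ± 0.98) and CG9757 (6.23 ± 0.70) were among the largest rises in the authors' deposited table. The germline RNA helicase vas was at 1.92 ± 0.31 in the authors' deposited table, with 2 of 27 germline genes higher and 1 lower (adjusted p = 1 for both). The authors' DESeq2 table listed 1208 of 12131 genes tested, 941 higher and 267 lower, and at least 3270 passed its adjusted p limit. At an absolute log2 fold change of at least 2 it held 436, of which 91.3% were higher against 77.9% of all listed genes, and the calls of muscle and of lower glue genes ended. With listed genes as background the muscle and immune calls ended, and at an adjusted p limit of 0.001 the muscle call did.

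Over the deficiency, larvae with wild-type l(3)mbt already differed from Oregon-R in testis, muscle, cuticle and immune genes. Of 39 testis genes, 24 rose and none fell (one-sided Fisher's exact test, adjusted p = 1.1e-10), although the labels give all larvae as female. The sperm leucyl aminopeptidase S-Lap3 was at 5.98 ± 1.48, and the sperm genes dj (22.67 ± 2.13), ProtB (22.70 ± 2.40) and Mst84Da (23.16 ± 2.69) had fitted values above 10 in the authors' deposited table. Muscle genes were 17 of 26 higher (adjusted p = 2.5e-08), such as the titin-like sls (1.76 ± 0.30), Mf (1.81 ± 0.33), Mhc (3.18 ± 0.61) and TpnC47D (3.40 ± 0.69) in the authors' deposited table. Cuticle genes were 36 of 67 higher (adjusted p = 4.0e-13), detoxification genes 30 of 73 (adjusted p = 7.2e-08) and digestive enzymes 18 of 53 (adjusted p = 0.00096), while 2 detoxification genes were lower. Cpr78Cc (8.08 ± 1.09), Lcp65Ac (3.24 ± 0.42), Cyp4p2 (4.04 ± 0.24), Cyp4p1 (2.49 ± 0.26) and Jon25Biii (3.38 ± 0.28) were examples in the authors' deposited table. Immune genes were 14 of 49 lower (adjusted p = 2.5e-14) and 2 higher, with LysD (-3.31 ± 0.49), LysP (-2.74 ± 0.44) and LysB (-3.74 ± 0.61) lower and the recognition protein PGRP-SD (2.24 ± 0.25) higher in the authors' deposited table. Germline lists had few called members, 3 of 27 piRNA genes, 3 of 27 germline genes and 2 of 23 meiosis genes higher (adjusted p = 1 for each). The authors' deposited table had SoYb at 1.75 ± 0.23, fs(1)Yb at 1.63 ± 0.56, mael at 1.15 ± 0.42, TrxT at 5.68 ± 1.40, exu at 1.46 ± 0.48 and orb at 1.21 ± 0.59. The eye pigment transporter gene st was at 2.19 ± 0.51 in the authors' deposited table. The authors' DESeq2 table listed 1862 of 12929 genes tested, 1716 higher (92.2%) and 146 lower. A mean signal of at least 50 left 1066, and the digestive call ended with listed genes as background.

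Germline genes were among the higher genes with either l(3)mbt allele over the deficiency, and in GM76/Df beyond what the wild-type copy over it and other genes gave. The transcript of l(3)mbt, at 3R 27266326 to 27273273, was listed in PBac/Df (-1.69 ± 0.10, 3.24-fold lower in the authors' deposited table) and not in GM76/Df or WT/Df. In GM76/Df, piRNA pathway genes were 12 of 27 higher (one-sided Fisher's exact test, adjusted p = 0.00030), germline genes 13 of 27 (adjusted p = 5.4e-05) and meiosis genes 10 of 23 (adjusted p = 0.0015). In PBac/Df the counts were 12, 12 and 10 (adjusted p = 0.051, 0.051 and 0.10), which did not pass against its larger number of higher genes. Argonaute AGO3 rose by 4.41 ± 0.22 in GM76/Df and 3.95 ± 0.24 in PBac/Df, vas by 5.34 ± 0.29 and 4.98 ± 0.31, and piwi by 3.54 ± 0.19 and 2.92 ± 0.21 in the authors' deposited tables. In the same order, the ovarian ribosomal protein gene RpS5b was at 5.49 ± 0.25 and 5.27 ± 0.27, Pxt at 7.28 ± 0.50 and 6.57 ± 0.53 and cup at 2.92 ± 0.27 and 3.13 ± 0.29 in the authors' deposited tables. The synaptonemal complex gene cona rose by 7.05 ± 0.57 and 7.07 ± 0.60, and the cohesion genes sunn by 4.26 ± 0.38 and 3.42 ± 0.40 and solo by 5.17 ± 0.58 and 4.92 ± 0.61 in the authors' deposited tables. Taken as 1 set of 76 piRNA, germline and meiosis genes, 34 were higher in GM76/Df, 33 in PBac/Df and 8 in WT/Df. Of these, 27 were called in GM76/Df and not WT/Df against 1 the other way where all genes split 472 to 669 (two-sided Fisher's exact test against other genes, adjusted p = 1.2e-08, chosen after the results were seen). For PBac/Df it was 25 against 0 where all genes split 1330 to 108, which did not pass (adjusted p = 0.60). Even with 0 the other way these 25 genes could not pass, so the test decides nothing for PBac/Df.

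**Figure D2:**
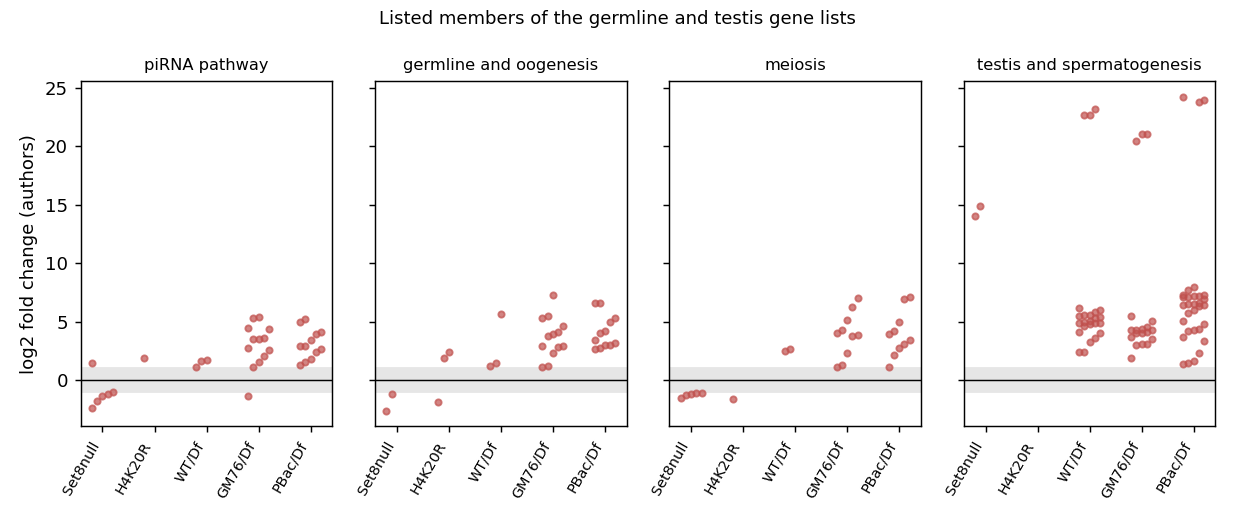
Log2 fold changes of the listed members of 4 gene lists (1 point per gene) against Oregon-R for Set8null, WT/Df, GM76/Df and PBac/Df and against HWT for H4K20R. The grey band marks the range from -1 to 1 that the tables leave out, and values above 10 are fitted ones that give no size; piRNA genes were 12 of 27 higher in both alleles and testis genes 24, 19 and 31 of 39 in WT/Df, GM76/Df and PBac/Df.

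Testis genes were 19 of 39 higher in GM76/Df (one-sided Fisher's exact test, adjusted p = 3.5e-07) and 31 of 39 in PBac/Df (adjusted p = 1.9e-12). Testis genes called in PBac/Df and not WT/Df numbered 7 against 0 the other way, and in GM76/Df 2 against 7, and neither split differed from that of other genes (two-sided Fisher's exact test, adjusted p = 1 and 0.70). Where all genes split 1330 to 108, even 7 against 0 could not pass, so the test decides nothing for PBac/Df. The Y-linked fertility genes kl-5 (5.99 ± 2.15), kl-3 (5.67 ± 2.44) and kl-2 (4.86 ± 2.42) were listed in PBac/Df in the authors' deposited table, 3 of the 13 male-specific genes (adjusted p = 1), of which 0 were called in WT/Df or GM76/Df. Immune genes were 15 of 49 lower in GM76/Df (adjusted p = 1.1e-10) and 17 in PBac/Df (adjusted p = 1.9e-10), while 10 and 3 were higher (adjusted p = 0.33 and 1), with LysP at -10.50 ± 0.64 (a fitted value) and -6.38 ± 0.44 in the authors' deposited tables. In PBac/Df the antimicrobial peptide genes Mtk (-3.73 ± 0.62) and DptA (-4.99 ± 0.84) fell, and in GM76/Df BomS3 (4.60 ± 0.65) rose in the authors' deposited tables. Muscle genes were 13 of 26 higher in GM76/Df (adjusted p = 3.2e-05) and 17 in PBac/Df (adjusted p = 3.2e-05), and cuticle genes 32 and 38 of 67 (adjusted p = 2.8e-11 and 1.3e-08). Digestive enzymes were 25 and 24 of 53 higher (adjusted p = 7.8e-09 and 0.0012) and detoxification genes 28 and 32 of 73 (adjusted p = 1.4e-07 and 0.00025). In the same order, 4 and 5 cuticle, 4 and 3 digestive and 3 and 2 detoxification genes were lower. Examples from the authors' deposited tables, GM76/Df first, were sls (1.60 ± 0.28 and 2.05 ± 0.30), Ccp84Aa (5.63 ± 0.79 and 7.12 ± 0.82), the mannosidase LManIII (5.95 ± 0.56 and 6.36 ± 0.60) and Cyp6w1 (5.76 ± 0.47 and 5.14 ± 0.50). Patterning genes were 8 of 32 lower in PBac/Df (adjusted p = 0.00043), among them eya (-1.21 ± 0.17) and dac (-1.23 ± 0.25) in the authors' deposited table. Glue genes were 5 of 12 lower (adjusted p = 0.00081) and 4 higher (adjusted p = 0.90) in PBac/Df, with Sgs5 at -3.21 ± 0.38 in the authors' deposited table. The germline histone variant BigH1 was at 2.97 ± 0.88 in GM76/Df, 2.85 ± 1.01 in PBac/Df and 2.48 ± 1.07 in WT/Df in the authors' deposited tables, the 1 called gene of 16 on the histone list (adjusted p = 1 for each), and no canonical histone gene was listed. The authors' DESeq2 tables listed 1877 of 12664 genes tested for GM76/Df, 1519 higher and 358 lower, and 3502 of 13461 for PBac/Df, 2938 higher and 564 lower. A mean signal of at least 50 left 1925 in PBac/Df. In PBac/Df the detoxification, digestive and cuticle calls ended with listed genes as background, and the detoxification, digestive, muscle, glue and patterning calls ended at a log2 fold change of at least 2, as did the muscle call in GM76/Df. Without the genes listed in WT/Df, the calls of lower immune genes and of higher detoxification, cuticle and muscle genes ended in both alleles, as did the testis call in GM76/Df and the digestive call in PBac/Df. The testis call in PBac/Df did not end.

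Tested directly against WT/Df, the alleles differed in a mucin, a lysozyme and the Yb-body gene SoYb. By z from the authors' deposited tables, Muc14A was 5.58 ± 0.36 log2 units higher in GM76/Df than in WT/Df (6.61 ± 0.23 against 1.03 ± 0.28) and 4.70 ± 0.37 higher in PBac/Df. The same 6 genes led for both alleles. The GM76/Df minus WT/Df differences from the authors' deposited tables were -7.77 ± 0.77 for LysP (from a fitted value above 10 in size, so not read as a size), 3.26 ± 0.39 for CG6999, 2.57 ± 0.34 for the tetraspanin family gene TM4SF and 1.75 ± 0.30 for SoYb. For PBac/Df minus WT/Df these differences from the authors' deposited tables were -3.65 ± 0.62, 3.06 ± 0.40, 2.90 ± 0.35 and 1.67 ± 0.31. The receptor tyrosine kinase gene tor changed sign, at 2.48 ± 0.32 in GM76/Df and 1.74 ± 0.36 in PBac/Df against -1.48 ± 0.47 in WT/Df in the authors' deposited tables. In all, 24 of 1143 genes in both tables differed for GM76/Df (15 higher, 9 lower) and 18 of 1713 for PBac/Df (13 higher, 5 lower). With the covariance from the shared Oregon-R libraries subtracted, the counts were 61 and 116. These counts are approximate, since the fold changes and standard errors do not give the authors' p-values. Median differences over the shared genes were -0.19 for GM76/Df and 1.05 for PBac/Df.

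Set8null and both alleles shared changes in individual genes that WT/Df did not list. Set8null and both alleles had 715 genes in the same direction, 618 higher and 97 lower, and WT/Df also listed most of them. The 177 that it did not list were 120 higher and 57 lower. The 10 with the strongest calls included Unc-115b, which was at -4.81 ± 0.25 in Set8null, -4.65 ± 0.25 in GM76/Df and -4.69 ± 0.27 in PBac/Df in the authors' deposited tables. CG8677 (-2.04 ± 0.12 in Set8null), CG9577 (-2.04 ± 0.14), the mitochondrial ribosomal protein gene mRpL37 (-2.06 ± 0.15) and CG42633 (-6.49 ± 0.79) also fell in the authors' deposited tables. CG14695 (3.43 ± 0.32 in Set8null), CG5961 (2.07 ± 0.16), Nepl11 (4.66 ± 0.51), Arc1 (1.88 ± 0.13) and the unconventional myosin Myo31DF (1.29 ± 0.15) rose in the authors' deposited tables. Across pairs, genes called in both comparisons mostly had the same direction. Of 535 genes in both Set8null and H4K20R, which share no library, 515 (96.3%) did, and 487 were higher in both where independent lists would share 74.6 (one-sided Fisher's exact test, adjusted p under the smallest number that could be written). For Set8null and GM76/Df it was 780 of 802 genes (97.3%), with 663 higher in both against 115.4 for independent lists, and for Set8null and PBac/Df 885 of 911. GM76/Df and PBac/Df shared 1662 of 1663 genes in direction, and WT/Df shared 1141 of 1143 with GM76/Df and 1711 of 1713 with PBac/Df. Unchanged groups simulated against the shared Oregon-R libraries gave 2.60 shared genes for Set8null and GM76/Df, 2.76 for Set8null and PBac/Df, 2.81 for the 2 alleles, 2.12 for WT/Df and GM76/Df and 2.66 for WT/Df and PBac/Df, 100% of them in the same direction, and part of the excess may come from the shared controls. Set8null and Set8RG had the same direction for 66 of 71 genes, with 54 higher in both against 7.47 for independent lists (adjusted p = 1.4e-35). H4K20A and H4K20R did so for 33 of 35 genes, with 24 higher in both against 3.49 (adjusted p = 1.6e-15) and 0.135 shared genes in simulation. The same direction was less common for H4K20A with Set8null (28 of 36), WT/Df (24 of 42), GM76/Df (28 of 52) and PBac/Df (26 of 53), and for Set8RG with the last 3 (27 of 43, 53 of 69 and 55 of 75). H4K20A had 47.3% of its listed genes higher and Set8RG 68.2%, against 92.2% in WT/Df. Such unlike shares alone lower agreement in direction, so it is not read as a difference in regulation. Npc2h, TotC and CG30026 were the 3 genes listed as higher in all of Set8null, Set8RG, H4K20A and H4K20R, with Npc2h at 1.77 ± 0.34, 1.44 ± 0.40, 2.40 ± 0.37 and 4.05 ± 0.34 in the authors' deposited tables, a set chosen after its values were seen. Of 42 tests of overlap, 41 passed, the exception being genes lower in Set8RG and WT/Df, where 0 were shared. With listed genes as background 9 of the 41 ended, 5 of them pairs with H4K20A, and genes lower in both Set8null and H4K20R were among them.

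Genes beside l(3)mbt were lower in all 3 deficiency genotypes. TfIIA-L, a general transcription factor subunit at 3R 27251112 to 27256463, was at -1.04 ± 0.08 in WT/Df, -1.06 ± 0.08 in GM76/Df and -1.02 ± 0.08 in PBac/Df in the authors' deposited tables. CG5938, 1.52 kb from l(3)mbt at 3R 27274794 to 27277418, was at -1.22 ± 0.13, -1.37 ± 0.12 and -1.28 ± 0.13 in the authors' deposited tables. The neighbours woc (-1.03 ± 0.09 in WT/Df) and CG5934 (-1.19 ± 0.14 in GM76/Df) were each in 1 of the authors' deposited tables, close to its fold limit. RYa-R, 208 kb away, was at -2.43, -5.16 and -4.42 in the same order in the authors' deposited tables. These neighbours were named after their values were seen. Within 500 kb of l(3)mbt, WT/Df listed 4 lower and 17 higher genes, against 142 and 1699 elsewhere (two-sided Fisher's exact test, adjusted p = 0.54). Of 21 such Fisher's exact tests near l(3)mbt, Set8 or the histone cluster, 0 passed after adjustment and 0 had an unadjusted p under 0.05, the smallest being 0.0762. The fold limit of the tables lies at the size that 1 lost copy would give.

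**Figure D3:**
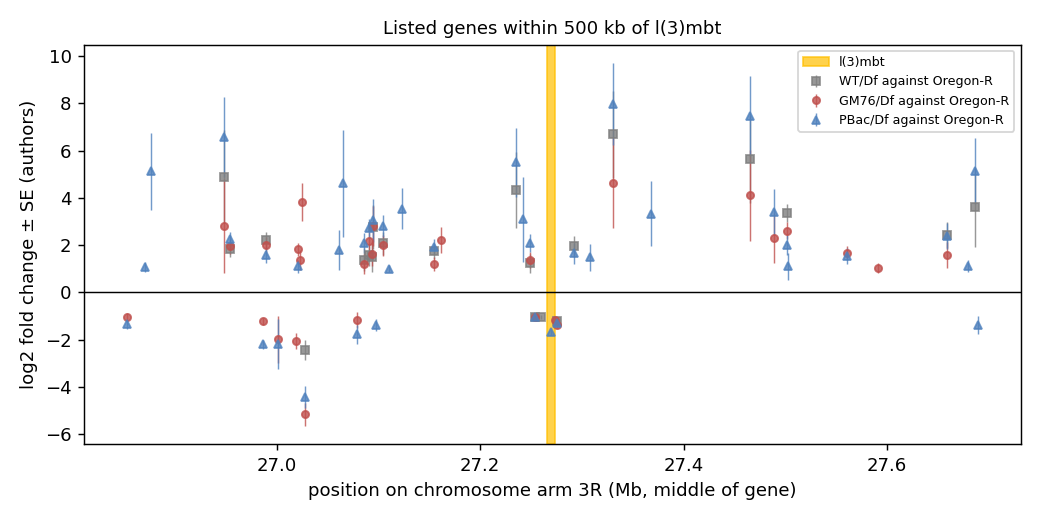
Log2 fold change ± standard error of listed genes within 500 kb of l(3)mbt (yellow band) by position on 3R in Mb, for WT/Df (squares), GM76/Df (circles) and PBac/Df (triangles) against Oregon-R. TfIIA-L and CG5938 beside l(3)mbt lie between -1.37 and -1.02 in all 3, and l(3)mbt itself is listed in PBac/Df alone.

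At 29 °C, most genes listed at a log2 fold change of 1 or more were lower than at 25 °C, and detoxification genes were among them in GM76/Df. In GM76/Df, 9 of 73 detoxification genes fell (one-sided Fisher's exact test, adjusted p = 3.7e-05), such as Cyp6w1 (-1.61 ± 0.43) and Cyp12a5 (-1.35 ± 0.31) in the authors' deposited table. The lysozymes LysD (-1.68 ± 0.43) and LysE (-1.52 ± 0.47), the larval serum protein Lsp1gamma (-1.40 ± 0.40), CG8160 (-4.01 ± 1.06) and CG32198 (-3.91 ± 1.65) also fell in the authors' deposited table. Rises there were small, the largest at a mean signal of at least 50 being CG10175 (1.28 ± 0.32) in the authors' deposited table. In WT/Df, 4 of 73 detoxification genes were listed as lower, which did not pass (adjusted p = 0.083), GstD2 (-1.93 ± 0.76) and GstD5 (-1.53 ± 0.72) among them in the authors' deposited table. Cpr47Eg (-7.25 ± 2.56), the yolk protein Yp3 (-2.28 ± 1.17) and CG10581 (-2.51 ± 0.47) fell and krimp, named after its value was seen, rose by 1.48 ± 0.23 in the authors' deposited table. CG7924 (5.05 ± 4.33) and CG34193 (4.12 ± 4.41) were listed as higher in the authors' deposited table with standard errors close to the fold. In PBac/Df the authors' deposited table listed CG7916 (1.06 ± 0.25) as higher and genes such as PGRP-SB2 (-12.68 ± 6.18), CG43120 (-4.81 ± 2.12) and TwdlO (-4.66 ± 3.04) as lower. The authors' DESeq2 tables listed 75 genes for WT/Df (9 higher), 144 for GM76/Df (11 higher) and 8 for PBac/Df (1 higher). WT/Df and GM76/Df shared 6 lower genes against 0.833 for independent lists (adjusted p = 0.0028), and Bonferroni adjustment left 25 and 33 genes. At an absolute log2 fold change of at least 2, WT/Df held 13 genes, 6 higher and 7 lower, GM76/Df 2 and PBac/Df 4, so the lean to lower genes did not hold in WT/Df at that fold.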

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

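The tests of the 3 patterns below, the bound that leaves the testis test undecided, the reading of the germline test, and the z tests between histone substitutions and between Set8 contrasts were chosen after the results had been seen, and the z tests at 29 °C were planned. No library was tested as an outlier and no regrouping of libraries was run, because no values per library were analysed here.

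The same gene moved differently in related contrasts by z on the authors' deposited tables, with Benjamini-Hochberg adjustment. Between the histone substitutions, 11 of 35 shared genes differed (4 at an adjusted p limit of 0.01), by approximate p-values, led by LysD (H4K20A minus H4K20R -6.22 ± 0.74), LysE (-5.40 ± 0.78) and CG32640 (-5.53 ± 1.44). LysD and LysE fell in H4K20A and rose in H4K20R (1.21 ± 0.53 and 1.39 ± 0.56) in the authors' deposited tables. Between Set8null and Set8RG, 22 of 71 shared genes differed (18 at 0.01). The transporter gene Oatp58Db (-6.55 ± 0.62), the cytochrome P450 gene Cyp12c1 (3.45 ± 0.35) and the phosphatase gene Alp7 (-10.71 ± 1.21), given as Set8null minus Set8RG, led and changed in opposite directions in the authors' deposited tables. For 29 °C, CG10581 was the 1 of 6 shared genes that differed, by 1.45 ± 0.55 for GM76/Df minus WT/Df (adjusted p = 0.047, 0 at 0.01). For PBac/Df minus WT/Df at 29 °C it was CG32762 of 2 shared genes, by -25.96 ± 7.25 (adjusted p = 0.00068), a difference of fitted values that is not read as a size.

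Testis transcripts were higher in all 3 deficiency genotypes of larvae labelled female. Complete loss of l(3)mbt is argued against as the whole cause, since 24 of 39 testis genes were higher with a wild-type copy. Unusually low Oregon-R libraries are argued against by Set8null, where 2 of the 39 were higher against the same Oregon-R libraries (22 called in WT/Df alone and 0 in Set8null alone, where all genes split 1172 to 418; two-sided Fisher's exact test, p = 0.0022). A single source of testis RNA present at a larger share in PBac/Df may remain: the PBac/Df minus WT/Df difference lay between 0.78 and 2.15 log2 units for all 24 genes (Cochran's Q against chi-square, p = 1). The WT/Df values of dj, ProtB and Mst84Da among them are fitted ones above 10, so their differences are not read as sizes. The median difference over all 1713 shared genes was 1.05, and with a median standard error of 1.62 (covariance of shared libraries subtracted) or 2.13 (taken as independent) that test had little power, so this source and a genotype effect cannot be told apart. Testis genes also differed without the deficiency or Oregon-R, with 4 of 39 lower in H4K20A than in HWT (one-sided Fisher's exact test, adjusted p = 0.00024). That call ended at the stricter adjusted p limit, and 0 of the 39 were called in Set8RG or H4K20R. Differences in testis transcripts were therefore not confined to the deficiency genotypes, and their source in H4K20A was not tested. Of 13 male-specific genes, 0 were called in WT/Df and in GM76/Df and 3 in PBac/Df, and of 23 Y-linked coding genes 1, 0 and 6 were higher. The 6 Y-linked genes in PBac/Df go with some male larvae in those pools. That count was close to the 4.81 expected from the share of all genes higher there, so it does not settle the question. For WT/Df and GM76/Df male larvae stay open, since genes that are not listed have no value here. The non-coding roX1 and roX2 on that list may not have been testable, since all 4609 listed genes matched to the annotation were protein-coding.

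Germline genes were called higher in both l(3)mbt alleles, more than other genes in GM76/Df, while the test could not decide this in PBac/Df. The shared deficiency background is argued against as the whole cause in GM76/Df by the lower count in WT/Df (two-sided Fisher's exact test against other genes, p = 4.9e-10). In PBac/Df other genes were also mostly called in PBac/Df alone. There the most extreme split, 25 against 0, gave p = 0.25 in the same exact test, which therefore could not decide. The 12 germline and oogenesis genes higher in PBac/Df ranged from 2.62 to 6.61 there (median standard error 0.50), and 9 of them were not called in WT/Df. A background effect of equal size and error would have passed the limits in WT/Df. For these 9 genes this argues against the shared background as the whole cause, although their WT/Df values are not known. A larger share of germline tissue is a possible explanation that stays open: the 12 germline genes higher in both alleles ranged from 1.11 to 7.28 in GM76/Df and their folds varied beyond error in both (larger Cochran's Q p 3.0e-14). Transcripts also made outside the germline would rise less, which keeps it open beside an effect of the alleles.

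Many genes changed alike in Set8null, H4K20R and the deficiency genotypes, 350 of them higher and 14 lower in all 5. The shared Oregon-R libraries are argued against as the whole cause, because 96.3% of the genes in both Set8null and H4K20R, which share no library, had the same direction. Larvae of a younger stage may contribute: of the glue and Eig71E genes, 9 were lower in H4K20R and 5 in PBac/Df, and 18 calls over the 5 comparisons were higher, the new glue genes among them. How the new glue genes change with larval age was not measured here, so their rises are not read as going against a younger stage. Set8null had 4 higher and 0 lower, WT/Df 3 and 0, GM76/Df 4 and 1, PBac/Df 4 and 5, and H4K20R 3 and 9. No staging measure separates this from a genotype effect, so the explanations cannot be told apart.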

How the results depend on the processing

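Stricter limits of 0.001 on the adjusted p and 2 on the log2 fold change, and removal of the genes listed in WT/Df were chosen after the results had been seen, and the other settings were planned. The planned threshold of 0.01 and minimum log2 fold change of 1 equal the limits of the tables, so for counts, lists and overlaps they test nothing. No paired analysis was possible because the tables hold no values per library, and for the same reason fits with a replicate block, without each replicate, with another pseudocount or by other tools were not run. At an absolute log2 fold change of at least 2 the counts were 591 for Set8null, 41 for Set8RG, 51 for H4K20A, 436 for H4K20R, 1158 for WT/Df, 1026 for GM76/Df and 2197 for PBac/Df. At 29 °C they were 13 for WT/Df, 2 for GM76/Df and 4 for PBac/Df. The share of higher genes then moved to 91.3% in H4K20R (398 higher, 38 lower, from 77.9%), 46.2% in WT/Df at 29 °C (from 12.0%) and 0% in PBac/Df at 29 °C (from 12.5%). Bonferroni adjustment left 83 for Set8RG, 55 for H4K20A, 752 for H4K20R, 736 for WT/Df, 1065 for GM76/Df, 1910 for PBac/Df, 25 for WT/Df at 29 °C and 33 for GM76/Df at 29 °C. An adjusted p limit of 0.001 left 60 for H4K20A, 1213 for WT/Df, 37 for WT/Df at 29 °C and 61 for GM76/Df at 29 °C. A mean signal of at least 50 left 1066 for WT/Df and 1925 for PBac/Df. For the z tests against WT/Df, 15 genes differed for GM76/Df at 0.01, and subtracting the covariance gave 61 for GM76/Df and 116 for PBac/Df. With listed genes as background, odds ratios fell below 1 for genes lower in Set8null and H4K20R (0.914). They also did so for genes higher in Set8RG and WT/Df (0.753), Set8RG and PBac/Df (0.593) and H4K20A and PBac/Df (0.452), and for higher detoxification genes (0.864) and digestive enzymes (0.717) in PBac/Df. At an absolute log2 fold change of at least 2 that of lower cell cycle genes in Set8null was 0.992. Of 48 list calls, 14 ended at a log2 fold change of at least 2, 14 with listed genes as background, 7 at 0.001 and 2 at a mean signal of at least 50. Of 41 overlap calls, 4, 9, 1 and 1 ended in the same order. Removing the genes listed in WT/Df ended 10 of 17 list calls of the alleles and 4 of 30 overlap calls, and 4 list tests not called before became stronger. This removal takes away many background genes that share the Oregon-R controls, so those 4 are not read as new calls. Windows of 250 and 1000 kb left 0 calls near the loci. Of 466 calls of named genes, 30 were lost at a mean signal of at least 50, 92 under Bonferroni adjustment and 48 at 0.001. The cause of these shifts was not tested.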

Other observations

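The comparisons in this part were chosen after the results had been seen.

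Genes listed both at 29 °C in WT/Df or GM76/Df and in H4K20R or Set8null mostly had opposite directions. Of all listed genes, 12.0% were higher at 29 °C in WT/Df and 7.64% in GM76/Df, against 77.9% in H4K20R and 64.5% in Set8null. Such unlike shares alone make opposite signs common, here and in the counts with the deficiency genotypes at 25 °C. Of 83 genes listed both at 29 °C in GM76/Df and in H4K20R, which share no library, all 83 had opposite signs, and 81 were lower at 29 °C and higher in H4K20R against 11.6 for independent lists (one-sided Fisher's exact test, adjusted p = 5.0e-51). WT/Df at 29 °C gave 40 of 40 with H4K20R, and GM76/Df at 29 °C gave 58 of 63 with Set8null. Against its own genotype at 25 °C, where shared libraries act in that direction, it was 99 of 102 in GM76/Df, 64 of 64 in WT/Df and 1 of 3 in PBac/Df, while unchanged groups simulated with those shared libraries gave 0.415, 0.285 and 0.12 shared genes, all opposite. The other deficiency genotypes at 25 °C also gave mostly opposite directions. GM76/Df at 29 °C gave 98 of 101 with WT/Df and 113 of 114 with PBac/Df. WT/Df at 29 °C gave 43 of 48 with GM76/Df and 52 of 54 with PBac/Df. Some pairs with few shared genes went the other way. GM76/Df at 29 °C had the same direction in 3 of 4 genes with Set8RG and 3 of 4 with H4K20A. PBac/Df at 29 °C, with 8 genes listed, had the same direction in 2 of 2 with Set8null, 2 of 2 with H4K20R, 3 of 4 with WT/Df and 4 of 5 with GM76/Df. The genes lower in both were 3 with WT/Df (one-sided Fisher's exact test, adjusted p = 0.0011) and 4 with GM76/Df (adjusted p = 0.00099).

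Some genes recurred across genotypes. The receptor family gene mthl8 was at 11.53 ± 1.06 in Set8null, 10.59 ± 1.06 in H4K20A, 9.39 ± 1.03 in WT/Df, 10.04 ± 1.10 in GM76/Df and 10.54 ± 1.01 in PBac/Df in the authors' deposited tables. Its values above 10 are fitted ones that are not read as a size, and 4 of these 5 comparisons share the Oregon-R libraries. CG3397 was at -1.57 ± 0.34 in H4K20R, -2.19 ± 0.36 in GM76/Df and -2.74 ± 0.38 in PBac/Df in the authors' deposited tables, beside the larger losses with Set8. Ilp8 rose by 4.79 ± 0.75 in GM76/Df and 5.43 ± 0.79 in PBac/Df in the authors' deposited tables. The eye pigment transporter genes st and bw moved apart, with st at 2.63 ± 0.46 and bw at -2.38 ± 0.48 in H4K20R in the authors' deposited table. The remaining lists had few calls. Yolk and chorion genes had 2 of 19 lower in Set8null and in GM76/Df, and neuronal genes had 4 of 30 higher in GM76/Df (adjusted p = 1). The LINT and dREAM list had 1 of 14 lower in Set8null and 1 in PBac/Df, and the H4K20 list 1 of 3 in each, Set8 and l(3)mbt.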
